A study of Mus musculus with 8 samples.

How the data were processed

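The study measured total RNA from CH310T1/2 cells on GeneChip Mouse Genome 430 2.0 arrays, with 8 arrays in 4 groups of 2, over 2 days. The groups were taken from the sample labels, which number the arrays of each group 1 and 2 without saying whether they came from separate cultures.

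The deposited intensity values were made by the authors with RMA, which corrects background, normalizes by quantiles and summarises the probes of a probe set by median polish, and are given on the linear scale. The notes in the deposited workbook name Partek GS 6.6 for this step, while the series text names dChip of 2005, and the files do not settle which was used. The deposited ratio columns are the authors' ratios of group means, and the deposited p-value and q-value columns come from the authors' limma contrasts and QVALUE. These columns were used for comparison alone. The workbook and the series table hold the same intensities, with a largest relative gap of 4.99e-10. Raw images, detection calls and control probe sets (0 in the files) were not available, so signal over background could not be measured, and no genome was used.

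Intensities were transformed to log2, and all 45037 probe sets were tested without a filter. Of these, 37818 carry 1 gene symbol, 1399 several and 5820 none. For each of 20680 symbols the probe set with the highest mean stood for the gene. Symbols were checked against RefSeq names: 16151 were current, 2144 were synonyms and 2385 were not found. Symbols are printed as the array gives them.

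Group means were fitted with limma 3.58.1 (lmFit and eBayes) over the 8 arrays, with 4 residual degrees of freedom, 2.78 prior degrees of freedom and a prior SD of 0.168. The comparisons were Erg against control on day 0, on day 1 and averaged over both days, control day 1 against control day 0, and the Erg difference on day 1 minus that on day 0. P values were adjusted by the Benjamini-Hochberg method over all probe sets, with a threshold of 0.05. Every adjusted p for a gene or list is from limma, since the smallest exact permutation p for 2 arrays against 2 is 0.333. Errors are SD between arrays for group means and SE from limma for differences. The Erg differences of the 2 days were correlated over genes by Pearson and Spearman.

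The 22 gene lists, with 517 symbols of which 506 were measured, covered cartilage, hypertrophic cartilage and bone, joint, ETS family, endothelial, leukocyte, epithelial, adipocyte, skeletal muscle, smooth muscle, tendon and fibrous matrix, proteases, BMP and TGF-beta, Wnt, hedgehog, interferon, inflammatory cytokines and NF-kB, cell cycle, p53, unfolded protein and heat shock, immediate early, and hypoxia and glycolysis genes. Not measured were Snorc, Bglap, Gdf6, Plin1, Actc1, Adam19, Smad9, Isg15, Usp18, Sesn1 and Gapdh. Each list was tested with camera at a preset correlation of 0.01 between genes, adjusted over the 22 lists, and again with an estimated correlation and with fry.

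Genes are named by a fixed rule. It takes both Erg probe sets, 13 fixed genes (Sox9, Col2a1, Acan, Gdf5, Prg4, Wnt9a, Col10a1, Ihh, Runx2, Pthlh, Tnc, Fli1 and Ets1), and the 10 genes past the threshold that rose most and the 10 that fell most without overlap between the groups, or 5 each for the difference between the days. Where fewer than 5 passed, it takes the 5 with the smallest unadjusted p in each direction under the same condition, and from each list described the 2 to 4 members with the smallest p. Unnamed transcripts were left out. The groups, comparisons, lists, naming rule and most alternatives were chosen before the data were examined.

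The alternatives were the workbook values, an intensity trend in the variance model, a filter on dim probe sets, 1 probe set per symbol or the mean of all, a replicate block, the 4 arrays of a comparison alone, a second quantile normalization, cyclic loess, array weights, and each array left out in turn. A block with crossed replicate numbers on day 0 and some alternatives for the lists were added after the data were seen. The fit was tested on simulated data with 200 changed probe sets. It recovered 25.4% of 2-fold and 86.6% of 4-fold changes for Erg on day 0, and 20.9% and 74.6% between control days. The rates were 65.7% and 94.0% for the average, and 0% and 43.3% for the difference between the days. These rates describe the simulated data and may not carry over to the real arrays. There, the Erg arrays of day 0 differed with an SD of 0.611, against 0.233 to 0.335 in the other groups. Between the control days 8922 probe sets passed, against 200 changed in the simulation. R 4.3.3, data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9 were used, with seed 1.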

Results

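Messenger RNA levels were measured on 8 GeneChip Mouse Genome 430 2.0 arrays, each hybridised with total RNA from CH310T1/2 cells, the spelling the labels use for this mouse mesenchymal cell line. The cells were grown as micromass cultures, dense spots of cells used to study cartilage formation, after electroporation with a plasmid for Erg-010, a form of the ETS family transcription factor Erg, or with a control plasmid. The arrays form 4 groups of 2: control on day 0, Erg on day 0 with the CMV promoter, control on day 1, and Erg on day 1 with the Col2 promoter. Promoter and day changed together, so their contributions to any difference between the days cannot be told apart. The series title places the work on the part Erg plays in the fate of cartilage cells as the knee joint forms. Each array gave a value for 45037 probe sets, with array medians between 6.59 and 6.70 on the log2 scale, and the number of arrays limits the precision of every comparison. No label says whether the 2 arrays of a group came from separate cultures, so the p-values of genes describe the spread between these arrays, which may be technical. The camera p-values compare a list with the other genes, at a preset correlation of 0.01 between genes. The estimated correlation was 0.47 for the interferon list, and from 0.0077 (inflammatory) to 0.68 (cell cycle) over the lists. With the estimated correlation 0 lists passed in every comparison, even where all 30 interferon members fell between the control days. Failing that test therefore cannot tell lists that moved from lists that did not.

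The arrays separated first by day. The first principal component held 65.8% of the variance and placed the day 0 arrays between -71.9 and -50.6 and the day 1 arrays between 53.8 and 79.4. On the second component, with 20.5% of the variance, Erg day 0 replicate 2 lay at -84.1, while the other day 0 arrays lay between 4.61 and 42.5. The log2 values of the 2 Erg arrays of day 0 differed with an SD of 0.611 over the probe sets. That SD was 0.260 for the day 0 controls, 0.335 for the day 1 controls and 0.233 for the Erg arrays of day 1.

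**Figure D1:**
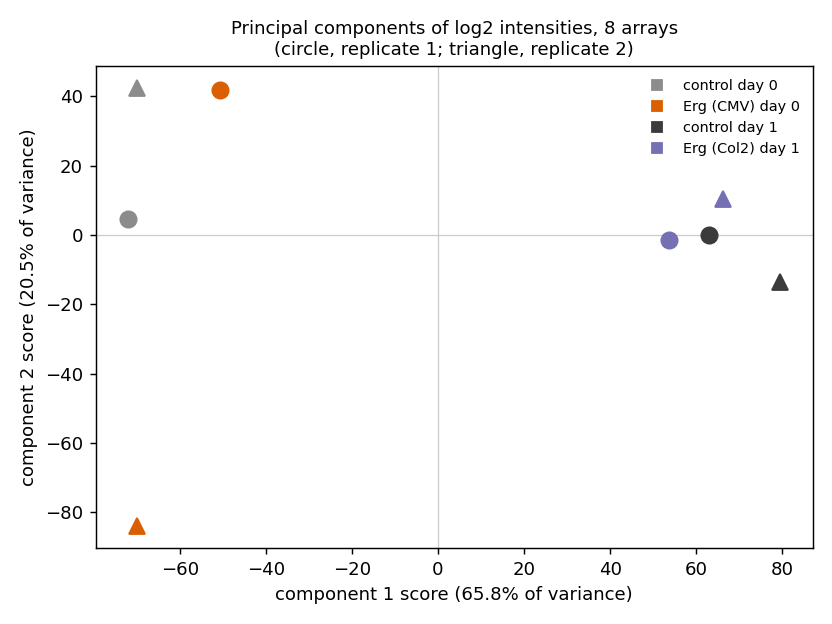
Scores of the 8 arrays on the first 2 principal components of the log2 values, with 1 point per array and the axes giving the share of variance, 65.8% and 20.5%. Day separates the arrays along the first axis, and Erg day 0 replicate 2 lies at -84.1 on the second.

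Erg itself was not higher in the arrays labelled Erg. The probe set with the shorter interval, on chromosome 16 from 95580775 to 95581556, read 7.45 ± 0.21 (SD, n = 2) on the log2 scale in the day 0 controls and 6.19 ± 0.85 in the day 0 Erg arrays. On day 1 it read 8.46 ± 0.05 in the controls and 8.11 ± 0.60 in the Erg arrays. The probe set with the longer interval, from 95581816 to 95808200 on the same chromosome, read 6.93 ± 0.15 and 6.79 ± 0.24 on day 0, and 7.11 ± 0.14 and 7.02 ± 0.29 on day 1. Ensembl records in 11721 rows of the annotation name genome build 37, but it is not stated that these alignment positions use it. The sequence of the plasmid is not given either, so whether either probe set reads the plasmid transcript is unknown. The differences for the shorter interval were -1.26 (SE 0.42, adjusted p = 0.802) on day 0 and -0.36 (SE 0.42, adjusted p = 1) on day 1. Without Erg day 0 replicate 1, the day 0 difference was -1.87. Without Erg day 0 replicate 2, the array that stands apart, it was -0.66, with 1 Erg array left each time. The longer interval then read -0.31 and 0.03.

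**Figure D2:**
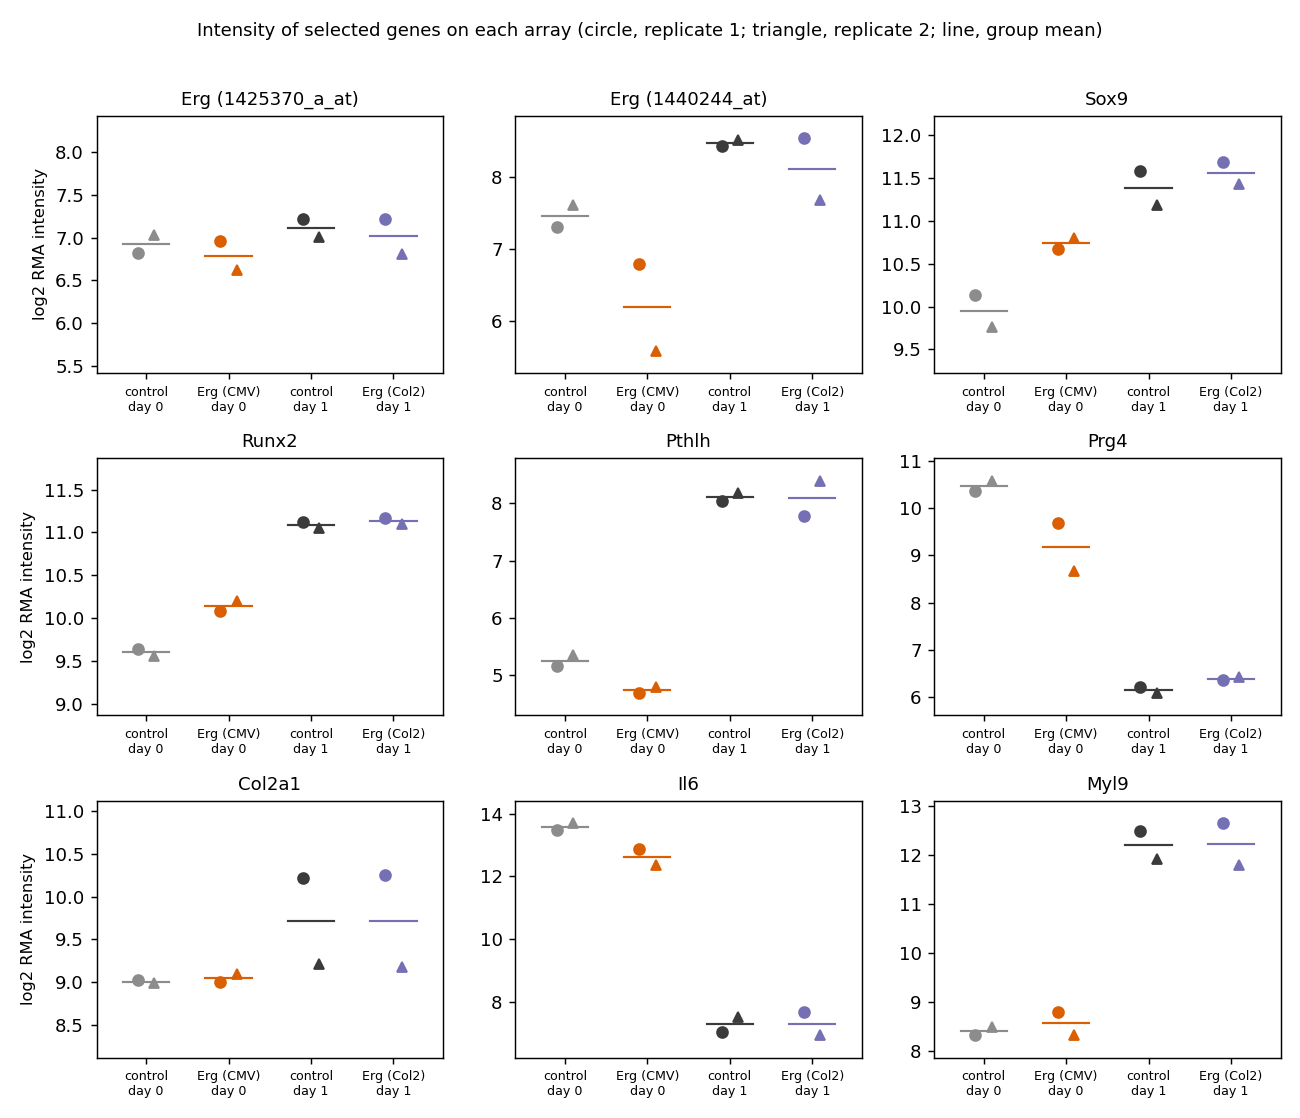
Log2 RMA intensity of 9 probe sets, including both for Erg, in each array, by group; circles are replicate 1, triangles are replicate 2 and the line is the group mean. Both Erg probe sets have lower means in the Erg groups, and Il6 and Prg4 read lower on day 1 than on day 0.

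On day 0, with the CMV promoter, the gene list with the smallest p for Erg was that of interferon response genes. Of the 30 measured members of that list, 29 read higher in the Erg arrays, with a median log2 difference of 0.72 and quartiles of 0.42 and 0.83. Oas2, an antiviral 2'-5'-oligoadenylate synthetase named by its small p, read 9.06 ± 0.004 (SD, n = 2) in controls and 9.94 ± 0.09 in Erg arrays, a difference of 0.88 (SE 0.12). Among list members, Oasl2 differed by 0.97 (SE 0.18) and Ddx58, a sensor of viral RNA, by 0.76 (SE 0.14). No single member passed the test over all probe sets, and 11 passed when adjusted over the list alone, all of them higher. As a set the list passed the camera test (adjusted p = 1.99e-19), but not when the correlation between genes was estimated (adjusted p = 0.966 with an estimated correlation, and from 9.83e-21 to 0.966 over the alternatives). In 22 members both Erg arrays lay above both controls and in 0 below both. For 1 gene, chance gives 33.3% for the 2 directions together. The members are correlated (0.47 when estimated), so the 22 cannot be read as independent results against that rate. The median difference was 0.37 without Erg day 0 replicate 2, with 1 Erg array left. The 2 controls themselves lay apart by a median of 0.30 over the list.

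Cartilage and joint genes gave mixed values on day 0, and none passed the test. Sox9, the regulator that starts chondrocyte development, read 9.95 ± 0.26 in controls and 10.74 ± 0.10 in Erg arrays, a difference of 0.79 (SE 0.20, adjusted p = 0.802). Runx2, a regulator of bone and hypertrophic cartilage, differed by 0.54 (SE 0.12). Prg4, the gene of the joint lubricant lubricin, read 10.48 ± 0.15 in controls and 9.17 ± 0.72 in Erg arrays, a difference of -1.30 (SE 0.30, adjusted p = 0.802). Pthlh, which holds back hypertrophy, differed by -0.51 (SE 0.21), and Fli1, the closest relative of Erg, by 0.48 (SE 0.15). The cartilage structural genes Col2a1 and Acan differed by 0.05 (SE 0.41) and -0.21 (SE 0.12). Gdf5 differed by -0.10, Wnt9a by 0.26, Col10a1 by -0.12, Ihh by -0.07, Tnc by -0.26 and Ets1 by 0.37. The cartilage, hypertrophic and joint lists had medians of -0.09, -0.12 and -0.17, and none of the 3 passed the camera test.

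Adipocyte markers were lower on day 0, with 15 of 19 members negative and a median of -0.31 (adjusted p = 0.0234, but adjusted p = 0.966 with an estimated correlation, and from 2.03e-04 to 0.966 over the alternatives). Cfd, the adipocyte protease adipsin, differed by -1.88 (SE 0.51) and Cd36, a fatty acid transporter, by -0.64 (SE 0.15), and neither passed. The list lost its call without control day 0 replicate 1 (median -0.32), and its median was 0.07 without Erg day 0 replicate 2. Among the genes chosen by smallest p, Kctd12 differed by 0.90 (SE 0.14), Dpy19l3 by 0.88, Gngt1 by -0.79 (SE 0.12), Tmsb10 by -0.68 (SE 0.13), Dync1i1 by -0.69 and Alpk1 by -0.61. In limma, 0 of 45037 probe sets passed an adjusted p of 0.05 on day 0, and 2444 (5.43%) had an unadjusted p under 0.05, 1069 higher and 1375 lower. A share of about 0.05 is expected where no probe set differs, so this count alone is no sign of a difference. Leaving out either Erg array of day 0 leaves 1, whose own spread cannot be measured, so only effect sizes are given here. Without Erg day 0 replicate 1, Prg4 was at -1.81, Cfd at -2.76, Runx2 at 0.60 and Oas2 at 0.94. Kctd12 was then at 0.95, Dpy19l3 at 0.88, Oasl2 at 1.01, Ddx58 at 0.77, Gngt1 at -0.90, Tmsb10 at -0.79 and Alpk1 at -0.69. Without Erg day 0 replicate 2, the array that stands apart, Prg4 was at -0.80, Cfd at -1.005 and Runx2 at 0.48. Over the 22 lists, 6 medians were positive, against 17 without Erg day 0 replicate 2, where 7 lists passed the camera test, all of them higher. Leaving out Erg day 0 replicate 1 instead, 6 lists passed, 2 of them higher.

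On day 1, with the Col2 promoter, no gene passed the test, and no gene list did with the deposited normalization, the 8 arrays and no block. Osr2, a transcription factor of developing joints, read 5.39 ± 0.23 (SD, n = 2) in controls and 6.08 ± 0.14 in Erg arrays, a difference of 0.69 (SE 0.20, adjusted p = 1). Tnc, the matrix protein tenascin C, differed by 0.57 (SE 0.29). Col27a1, a fibrillar collagen of cartilage, differed by -0.78 (SE 0.22), with both Erg arrays, at 9.95 and 9.93, below both controls, at 10.36 and 11.08. The other genes chosen by smallest p were Creb3l1 at 0.45 (SE 0.11), Klf5 at 0.60 (SE 0.18), Acy3 at 0.47, Tbc1d25 at 0.48, Pde4d at -0.92 (SE 0.28), C77405 at -0.50, C77626 at -0.48 and Clca3 at -0.37. C77626 and Clca3 read below the first quartile of every array (5.26 to 5.38). Pde4d and C77405 did so in all arrays but control day 1 replicate 2. Without detection calls, whether these 4 differences exceed background is unknown.

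The fixed cartilage and joint genes did not pass on day 1. Sox9 differed by 0.17 (SE 0.20), Prg4 by 0.23 (SE 0.30), Acan by 0.04, Gdf5 by 0.07, Wnt9a by 0.09, Runx2 by 0.05, Pthlh by -0.03, Col10a1 by -0.04 and Ihh by 0.02. Fli1 differed by 0.05 and Ets1 by -0.05, and Col2a1 had a mean of 9.71 in both groups. Its replicates lay apart: control and Erg read 10.21 and 10.25 in replicate 1, and 9.21 and 9.18 in replicate 2. The lowest list p values were those of the hypoxia and glycolysis list, with a median of 0.18, and the hedgehog list, with a median of 0.20 (adjusted p = 0.0559 for both). Members of these lists included the vasodilator peptide Adm at 0.34 (SE 0.20), Pfkp at 0.23, and the hedgehog regulators Sufu at 0.33 (SE 0.15) and Hhip at 0.25. The cell cycle list had a median of 0.20 and the interferon list one of 0.04. All 22 list medians were positive, against 17 after cyclic loess normalization, 14 without control day 1 replicate 2, 16 without Erg day 1 replicate 1 and 20 without Erg day 1 replicate 2. The median over all symbols was itself 0.042, and the cartilage (0.022), skeletal muscle (0.033) and interferon (0.039) medians lay below it. Lists passed the camera test in some other settings: 3 with a replicate block, 4 with a block within each day, 5 with crossed numbers on day 0, 4 with the 4 day 1 arrays alone and 4 after cyclic loess, all of them higher. Leaving out 1 array gave 6 without Erg day 1 replicate 1 (4 higher), 6 without Erg day 1 replicate 2, 4 without Erg day 0 replicate 1 and 4 without Erg day 0 replicate 2. With an estimated correlation, or under fry, 0 lists passed. In limma, 0 of 45037 probe sets passed and 616 (1.37%) had an unadjusted p under 0.05, 134 higher and 482 lower. That share is below the 0.05 expected where no probe set differs.

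Averaged over both days, which uses the day 0 arrays again, the interferon list median was 0.36, against 0.72 on day 0 and 0.04 on day 1 alone. In the average 28 of 30 members were positive, against 18 on day 1, and 4 passed when adjusted over the list alone. Ifi44 differed by 0.74 (SE 0.15, n = 4 against 4), Ddx58 by 0.52 (SE 0.10) and Oas2, outside the list, by 0.50 (SE 0.08). The list passed the camera test (adjusted p = 2.04e-13, but adjusted p = 0.997 with an estimated correlation, and from 1.38e-16 to 0.997 over the alternatives). Its median was 0.21 without Erg day 0 replicate 2, with 1 Erg array of day 0 left. ETS family genes other than Erg had a median of 0.12, with 17 of 24 members positive and 0 past the test over all probe sets or over the list alone (adjusted p = 0.0276 for the list, but adjusted p = 0.997 with an estimated correlation, and from 0.0123 to 0.997 over the alternatives). Fli1 differed by 0.27 (SE 0.10), Gabpa by 0.22, Etv3 by 0.31 and Erf, an ETS repressor, by 0.26. The ETS call was lost without Erg day 0 replicate 1 (median 0.14), Erg day 0 replicate 2 (0.10), control day 0 replicate 2 (0.10), Erg day 1 replicate 1 (0.10) or control day 1 replicate 2 (0.09). With the mean of all probe sets of a symbol, 1 list passed the camera test, against 2 in the main fit. A block within each day gave 3, and crossed numbers on day 0 gave 5.

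Among joint and cartilage genes the average differences were 0.48 (SE 0.14) for Sox9, 0.29 (SE 0.08) for Runx2, -0.54 (SE 0.22) for Prg4 and -0.27 (SE 0.15) for Pthlh. Col2a1 differed by 0.02, Acan by -0.08, Gdf5 by -0.02, Wnt9a by 0.18, Col10a1 by -0.08, Ihh by -0.02, Tnc by 0.15 and Ets1 by 0.16. The Erg probe sets differed by -0.81 (SE 0.30) for the shorter interval and -0.12 (SE 0.14) for the longer. Unc5c at 0.37, Adamtsl4 at 0.40, Dpm3 at -0.45, Nudt7 at -0.46, Cstad at -0.68, Dync1i1 at -0.41 and Fbxo8 at -0.48 had small unadjusted p values. In limma, 0 probe sets passed and 1581 (3.51%) had an unadjusted p under 0.05, 874 higher and 707 lower, again a share below 0.05. Prg4 was at -0.79 without Erg day 0 replicate 1 and at -0.28 without Erg day 0 replicate 2. Each time 1 Erg array of day 0 was left.

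Between day 0 and day 1 the control cultures changed widely, which describes the first day of micromass culture after electroporation. Il6, an inflammatory cytokine (chromosome 5 from 30339683 to 30346508), fell from 13.58 ± 0.16 (SD, n = 2) to 7.27 ± 0.33 on the log2 scale, and Ifi44, an interferon target (chromosome 3 from 151393888 to 151412911), fell from 11.18 ± 0.26 to 4.76 ± 0.19. Kctd12 rose from 5.23 ± 0.21 to 10.67 ± 0.08, the transcription factor Egr3 rose from 7.09 ± 0.08 to 11.04 ± 0.04, and Myl9, a myosin light chain of smooth muscle, rose from 8.41 ± 0.13 to 12.20 ± 0.40. Prg4 (chromosome 1 from 152296998 to 152312728) fell from 10.48 ± 0.15 to 6.15 ± 0.10, a difference of -4.32 (SE 0.30, adjusted p = 0.00191). In limma, 8922 of 45037 probe sets passed, 5334 higher and 3588 lower on day 1, and 3114 of the higher and 792 of the lower changed at least 2-fold. They stood for 2281 higher and 1915 lower symbols of 20680, and the median over all probe sets was -0.11. Day 0 RNA was on arrays numbered 1 to 4 and day 1 RNA on arrays 5 to 8, so day and array order cannot be told apart. With the 4 control arrays alone, 12533 passed in place of 8922. The Erg arrays enter this comparison only through the shared estimate of the spread. Leaving out either array of an Erg pair removes the spread of that pair, so both give the same count. Leaving out single arrays changed the count to 16506 without Erg day 0 replicate 1 and the same number without Erg day 0 replicate 2, to 812 without control day 0 replicate 1, 366 without control day 0 replicate 2, 4478 without control day 1 replicate 1, 2985 without control day 1 replicate 2, and 4762 without Erg day 1 replicate 1 and likewise without Erg day 1 replicate 2. The share that was higher, 59.8%, was 50.1% without Erg day 0 replicate 1 or without Erg day 0 replicate 2, and up to 79.0%, without control day 1 replicate 1.

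Interferon response genes fell together. All 30 members read lower on day 1, and 26 passed the threshold, 29 when adjusted over the list alone. The median was -1.87 (camera adjusted p = 2.84e-17, but adjusted p = 0.575 with an estimated correlation, and from 2.26e-22 to 0.575 over the alternatives). Besides Ifi44 at -6.41 (SE 0.22), Ifit1 changed by -4.72 (SE 0.19), Oas1a by -4.11 (SE 0.17), Bst2 by -3.30 (SE 0.12), Zbp1, a sensor of nucleic acids, by -4.87 (SE 0.21) and the chemokine Cxcl10 by -5.19 (SE 0.30). Ifi27l2a and Pyhin1, interferon-induced genes outside the list, changed by -4.33 (SE 0.35) and -4.42 (SE 0.91). Of the 26 inflammatory cytokine and NF-kB genes, 12 fell, 15 when adjusted over the list alone, and 0 rose, with a median of -0.64 (adjusted p = 5.12e-06, but adjusted p = 0.147 with an estimated correlation, and from 2.37e-07 to 0.147 over the alternatives). The chemokines Ccl7, Ccl2 and Cxcl1 changed by -4.75 (SE 0.34), -3.19 (SE 0.19) and -3.07 (SE 0.32). Leukocyte markers had a median of -0.35 (adjusted p = 0.0302), with 15 of 16 negative. Of this list 3 members passed, Cd68 at -1.60, Lyz2 at -0.66 and Cd53 at -0.54, and 0 when adjusted over the list alone. Its values were adjusted p = 0.575 with an estimated correlation, and from 6.28e-04 to 0.575 over the alternatives. Among single arrays left out, it lost its call without either Erg array of day 0 and without control day 0 replicate 2 (median -0.32). The leukocyte list was dim, with a median per array of 5.52 to 6.20, against array medians of 6.59 to 6.70. Signal over background was not measured.

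Cell cycle genes were lower, with 12 of 30 fallen, 13 when adjusted over the list alone, 0 risen, and a median of -1.20 (adjusted p = 0.00256, but adjusted p = 0.818 with an estimated correlation, and from 1.52e-06 to 0.818 over the alternatives). Ccnb2, a mitotic cyclin, changed by -2.99 (SE 0.58), the kinase Aurka by -2.45 (SE 0.56), Cdk1 by -1.45 (SE 0.33) and Plk1 by -1.30 (SE 0.26). Smooth muscle contractile genes were higher, with 6 of 16 risen and 0 fallen, 9 and 1 when adjusted over the list alone, and a median of 0.79 (adjusted p = 2.00e-04, but adjusted p = 0.630 with an estimated correlation, and from 2.12e-05 to 0.630 over the alternatives). Besides Myl9, the adhesion protein gene Vcl rose by 1.68 (SE 0.20), Synpo2 by 1.53 (SE 0.19) and the tropomyosin Tpm2 by 0.83 (SE 0.19). Of 13 hedgehog genes, 5 rose and 1 fell, 6 and 3 when adjusted over the list alone, with a median of 0.78 (adjusted p = 0.0302). The list had adjusted p = 0.678 with an estimated correlation, and from 3.58e-04 to 0.678 over the alternatives. After cyclic loess normalization it was 0.0771 and after a second quantile normalization 0.0689. The hedgehog receptor Ptch1 rose by 1.51 (SE 0.15), and the effectors Gli2 and Gli3 by 1.94 (SE 0.30) and 1.09 (SE 0.23).

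Cartilage genes moved in both directions, with 6 of 29 risen and 3 fallen, 7 and 5 when adjusted over the list alone, and a median of 0.26 (adjusted p = 0.0302, but adjusted p = 0.818 with an estimated correlation, and from 3.74e-05 to 0.818 over the alternatives). Sox9 rose by 1.44 (SE 0.20, adjusted p = 0.00722), the growth factor receptor Fgfr3 by 2.04 (SE 0.13) and Cytl1, a secreted protein of cartilage, by 2.08 (SE 0.18), while Ucma, a matrix protein of early chondrocytes, fell. Col2a1 at 0.71 (SE 0.41) and Acan at -0.38 (SE 0.12, adjusted p = 0.0707) did not pass, although Acan passed without Erg day 0 replicate 1 or without Erg day 0 replicate 2 (adjusted p = 0.0390 for each). The cartilage list lost its call without control day 0 replicate 1 (median 0.23, adjusted p = 0.0668) or control day 1 replicate 2 (0.22, adjusted p = 0.0672), and its adjusted p was 0.0677 after cyclic loess and 0.0563 after a second quantile normalization. Sox9 lost its call without control day 0 replicate 2, at 1.25 (adjusted p = 0.0689). In the joint list, 3 of 21 members rose and 2 fell, with a median of -0.25. Pthlh rose by 2.87 (SE 0.21, adjusted p = 0.00196), Osr1, a transcription factor of joint and limb mesenchyme, by 2.69 (SE 0.19) and Trps1, a repressor active in growth plates, by 1.75 (SE 0.25), while Prg4 fell. Gdf5 at -0.47 (SE 0.18), Wnt9a at -0.13 and Tnc at -0.45 (SE 0.29) did not pass. In the hypertrophic cartilage and bone list, Runx2 rose by 1.48 (SE 0.12, adjusted p = 0.00230), Ibsp, a bone sialoprotein, changed by -0.73 (SE 0.18), and the other 21 of 23 members, Col10a1 at 0.31 and Ihh at -0.13 among them, did not pass.

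**Figure D3:**
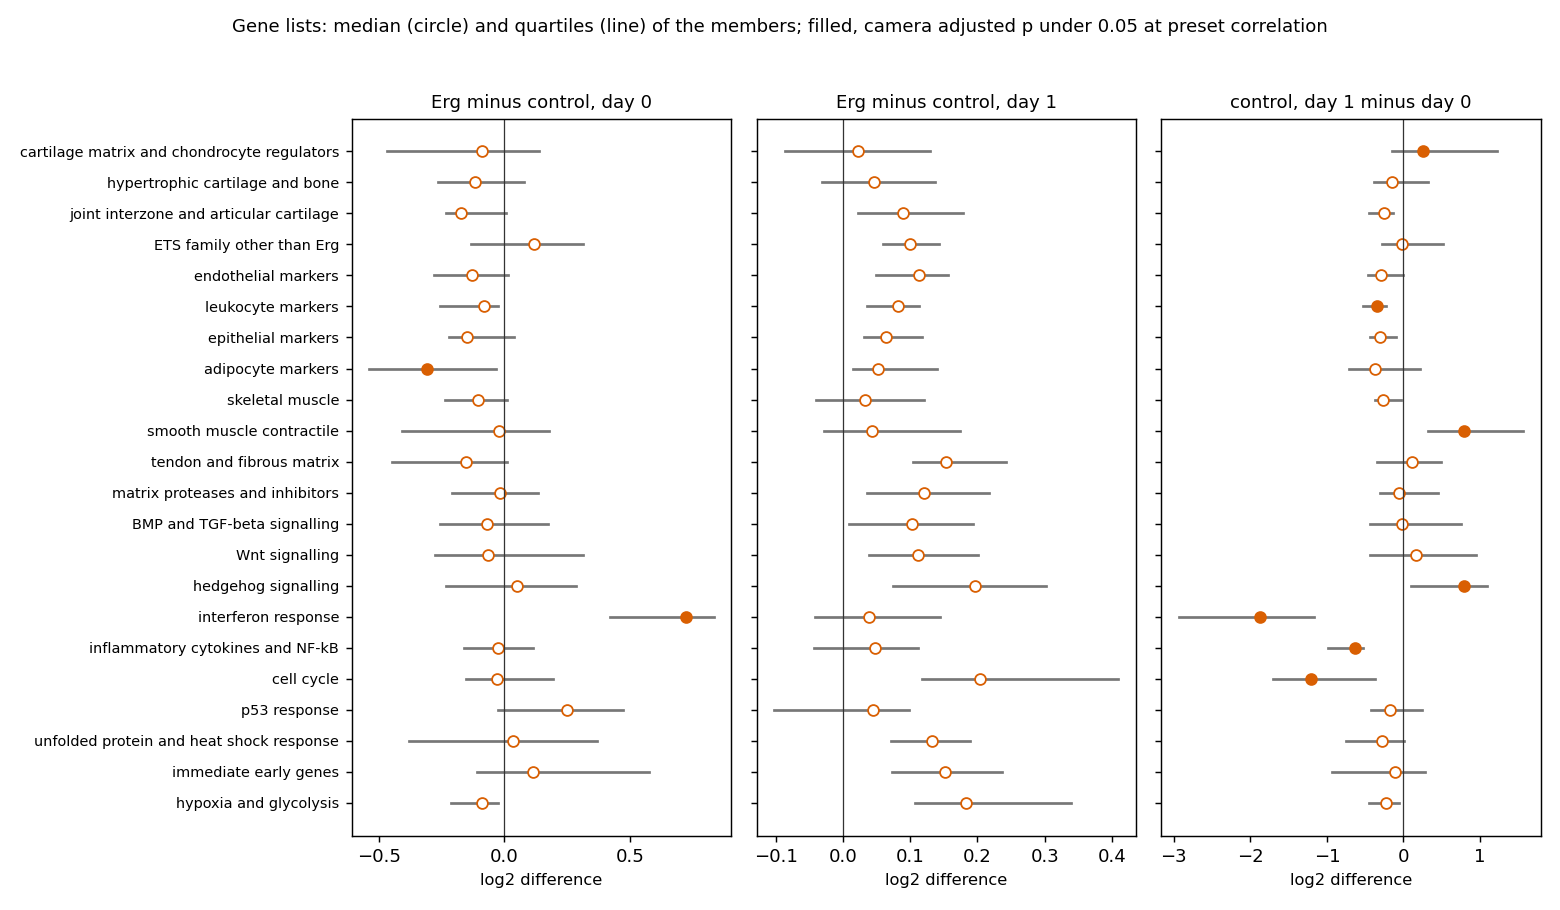
Median log2 difference of the members of the 22 gene lists (circles, with lines from quartile to quartile) for Erg on day 0, Erg on day 1 and control day 1 against control day 0; filled circles mark a camera adjusted p under 0.05, and the horizontal scale differs between panels. The interferon list has a median of 0.72 with Erg on day 0, 0.04 with Erg on day 1 and -1.87 from day 0 to day 1.

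Between the control days 7 of 22 lists passed the camera test, 3 of them higher and 4 lower. A second quantile or a cyclic loess normalization gave 4, 1 of them higher. Removing dim probe sets or using the 4 control arrays alone gave 6, 3 of them higher. In each of these settings fewer lists were called lower than in the main fit. The mean of all probe sets gave 6, 2 of them higher, and a replicate block 7, 3 of them higher. None of the remaining lists passed the camera test. Of 30 Wnt genes 9 rose and 2 fell, among them the ligand Wnt5b at 3.11 (SE 0.38), the antagonist Dkk2 at 2.85 (SE 0.36) and the effector Tcf7l2 at 2.35 (SE 0.20). Of 29 BMP and TGF-beta genes 8 rose and 4 fell, with Ltbp1 at 1.51 (SE 0.18) and the receptor Tgfbr2 at 1.31 (SE 0.23). Of 24 ETS genes other than Erg 5 rose and 1 fell, with Fli1 at 1.45 (SE 0.15) and Elk4 at 0.98 (SE 0.14), while Ets1 at 0.45 (SE 0.21) did not pass. Among 19 adipocyte markers 1 rose and 6 fell: Pparg, the regulator of fat cell formation, rose by 1.86 (SE 0.16), while Cfd changed by -2.86 (SE 0.51) and Cd36 by -1.20 (SE 0.15). Among 25 tendon and fibrous matrix genes 2 rose and 1 fell, with elastin, Eln, at 1.19 (SE 0.20) and the tendon regulator Mkx at -1.87 (SE 0.18). Among 29 matrix proteases and inhibitors 3 rose and 1 fell, with Adamts1 at 2.01 (SE 0.25) and Timp1 at -1.81 (SE 0.23).

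Of 32 endothelial markers 2 rose and 4 fell (median -0.29), with Ramp2 at 2.41 (SE 0.38) and Aplnr at -0.83 (SE 0.13), and of 16 epithelial markers 0 rose and 3 fell (median -0.31), with the keratin Krt18 at -0.74 (SE 0.14). Of 18 skeletal muscle genes 1 rose and 2 fell (median -0.27), with Tnni1 at 0.80 (SE 0.16). The median over all symbols was itself -0.15 between the control days. The endothelial, epithelial and skeletal muscle lists were also dim, with medians of at most 6.49 on any array. In the p53 list 1 of 19 rose and 2 fell, with the death receptor Fas at -2.63 (SE 0.29) and Gadd45a at -2.01 (SE 0.24). In the unfolded protein and heat shock list 0 of 21 rose and 1 fell, Manf at -1.30 (SE 0.31). Of 19 immediate early genes 2 rose and 3 fell, with Egr1 at 1.27 (SE 0.20) and Junb at -1.83 (SE 0.31), and of 21 hypoxia and glycolysis genes 2 rose and 1 fell, with Ndrg1 at 2.15 (SE 0.29) and Adm at -1.72 (SE 0.20). Median and mean differed in sign for the hypertrophic (-0.16 and 0.14), ETS (-0.02 and 0.13), protease (-0.06 and 0.04) and BMP and TGF-beta (-0.02 and 0.06) lists, and for the immediate early list (-0.11) the camera direction was up. Under fry, whose p asks whether a list moves on balance one way, the interferon (adjusted p = 0.00174), inflammatory (adjusted p = 8.90e-04) and leukocyte (adjusted p = 0.0189) lists passed in this comparison, and under its mixed test, which takes either direction, 21 of 22 did. No list passed either form in the Erg comparisons. Neither compares a list with other genes.

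The largest changes outside the lists included Fam107a at 5.46 (SE 0.90), Angptl1 at 5.31 (SE 0.77), Sned1 at 5.02 (SE 0.40), Pip at 4.17 (SE 0.67), Abi3bp at 4.08 (SE 0.42), AA407881 at 3.90 (SE 0.38) and AU042950 at 3.58 (SE 0.35), all of which rose, and the proto-oncogene Mycn at -4.36 (SE 0.45), which fell. The Erg probe sets differed by 1.01 (SE 0.42, adjusted p = 0.132) for the shorter interval and 0.18 (SE 0.20) for the longer, and the former passed without Erg day 0 replicate 1 or without Erg day 0 replicate 2 (adjusted p = 0.0258 for each). Probe sets of 1 gene sometimes differed: 2 of 3 for Sox9, 1 of 3 for Runx2 and 1 of 2 for Pthlh passed in the direction given, the other Wnt9a probe set passed with a fall, and the other Tnc probe set passed in the opposite direction. All 91 named results past the threshold kept their direction when single arrays were left out. Of these, 65 lost their call without control day 0 replicate 2, 54 without control day 0 replicate 1, 31 without control day 1 replicate 1, 31 without control day 1 replicate 2, 17 without Erg day 1 replicate 1 and 17 without Erg day 1 replicate 2. Fam107a had an adjusted p of 0.0929 without control day 0 replicate 2, 0.0714 without control day 0 replicate 1 and 0.0626 without control day 1 replicate 2. Pyhin1 had 0.101, 0.114, 0.0932 and, without control day 1 replicate 1, 0.0862. Angptl1 and Pip had 0.0731 and 0.0853 without control day 0 replicate 2, and 0.0624 and 0.0744 without control day 0 replicate 1. Abi3bp, AU042950 and Mycn lost their calls without control day 0 replicate 2 alone (0.0517, 0.0504 and 0.0545). The 26 that passed in every setting run for them, which for Pthlh and AA407881 left out the filter on dim probe sets, included Il6, Ifi44, Ifit1, Oas1a, Bst2, Zbp1, Cxcl10, Ccl2, Ccl7, Prg4, Mkx, Kctd12, Egr3, Myl9, Synpo2, Sned1, Pthlh, Osr1, Runx2, Fgfr3, Cytl1, Ptch1, Pparg and Tcf7l2.

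The Erg differences of the 2 days were then compared with each other. For the interferon list the difference on day 1 was below that on day 0 by a median of -0.57 over its members, from 0.72 on day 0 to 0.04 on day 1, with 29 of 30 members negative (adjusted p = 5.53e-18). The list had adjusted p = 0.934 with an estimated correlation, and from 1.13e-20 to 0.934 over the alternatives. Its median was -0.26 without Erg day 0 replicate 2, with 1 Erg array of day 0 left. Oasl2 gave -0.92 (SE 0.25), Psmb8, an immunoproteasome subunit, -0.73 (SE 0.27), and Oas2 -0.76 (SE 0.16). Prg4 gave 1.54 (SE 0.43), Sox9 -0.61 (SE 0.28), Runx2 -0.50 (SE 0.17), Tnc 0.83 (SE 0.41), Pthlh 0.48 (SE 0.30), Fli1 -0.43 (SE 0.21) and Ets1 -0.42 (SE 0.30). Kctd12 at -0.89, Dpy19l3 at -0.84, Fam102a at -0.78, Gngt1 at 1.16, Siglec1 at 0.75, Tmsb10 at 0.84, Adig at 0.88 and the growth factor gene Fgf8 at 0.69 had small unadjusted p values. Col2a1 at -0.05, Acan at 0.24, Gdf5 at 0.17, Wnt9a at -0.17, Col10a1 at 0.07 and Ihh at 0.08 had smaller values relative to their SE. In limma, 0 probe sets passed and 1100 (2.44%) had an unadjusted p under 0.05, 638 higher and 462 lower, again a share below 0.05. Without Erg day 0 replicate 1, Prg4 was at 2.05, Gngt1 at 1.27 and Cfd at 2.83. These 3 were at 1.03, 1.05 and 1.07 without Erg day 0 replicate 2. Each time 1 Erg array of day 0 was left.

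Another 6 lists differed between the days by the camera test, each with adjusted p = 0.934 with an estimated correlation, the highest over the alternatives. The lowest over the alternatives were 8.08e-05 for adipocyte, 0.00929 for endothelial, 1.27e-06 for tendon, 2.89e-05 for hypoxia, 0.0175 for joint and 2.88e-04 for p53 genes. The median differences were 0.34 for adipocyte markers (adjusted p = 0.00846), 0.19 for endothelial markers (adjusted p = 0.0217), and 0.37 for tendon and fibrous matrix, 0.28 for hypoxia and glycolysis, 0.17 for joint genes and -0.26 for the p53 list (adjusted p = 0.0428 for each). With the interferon list 7 lists passed, against 3 with the mean of all probe sets of a symbol and 4 with dim probe sets removed. Cyclic loess gave 4, a replicate block or a block within each day 6, and crossed numbers on day 0 or a second quantile normalization 7. Members with small p included Cfd at 1.95 (SE 0.71) and Cd36 at 0.69 (SE 0.22) among adipocyte markers, the nitric oxide synthase Nos3 at 0.39 (SE 0.16) among endothelial markers, Fmod at 0.80 (SE 0.44) among matrix genes, Bnip3 at 1.00 (SE 0.66) among hypoxia genes and Fas at 0.66 (SE 0.42), against the direction of its list, in the p53 list. Fmod and Bnip3 were at 1.32 and 1.80 without Erg day 0 replicate 1, and at 0.28 and 0.21 without Erg day 0 replicate 2. All 6 calls were lost without Erg day 0 replicate 2, where the medians were 0.01, 0.10, -0.01, -0.02, 0.04 and 0.15 in the order given. Without control day 0 replicate 1 the tendon (0.47), hypoxia (0.29) and joint (0.30) calls were lost, and without control day 0 replicate 2 the endothelial (0.15), tendon (0.30), hypoxia (0.25), joint (0.17) and p53 (-0.12) calls. Without control day 1 replicate 1 the adipocyte (0.35), hypoxia (0.42) and p53 (-0.24) calls were lost, and without control day 1 replicate 2 the endothelial (0.14), tendon (0.26), hypoxia (0.22), joint (0.15) and p53 (-0.305) calls. Without Erg day 1 replicate 1 the tendon (0.43) and hypoxia (0.21) calls were lost, and without Erg day 1 replicate 2 the adipocyte (0.28), endothelial (0.19), joint (0.15) and p53 (-0.21) calls.

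Across 20680 genes, which are not independent replicates, the Erg differences of the 2 days had a Pearson r of 0.110 and a Spearman rho of 0.129, and 52.6% of genes had the same sign on both days. The 2 differences share no array. Pearson r was -0.0726 without Erg day 0 replicate 1, -0.0521 without Erg day 1 replicate 1, -0.0913 without control day 1 replicate 2 and 0.0671 without control day 0 replicate 1. It was 0.385 without Erg day 0 replicate 2, 0.213 without Erg day 1 replicate 2 and 0.167 without control day 1 replicate 1.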

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

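For the interferon list on day 0, the tests on the array that stands apart and on the amount of DNA were chosen only after the result was seen, as were all tests on the Erg probe sets and on the lists that differ between the days. The split count for the number of probe sets and the splits balanced over days were also chosen afterwards.

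The interferon list was higher with Erg on day 0 by a median of 0.72, and the difference on day 1 was lower by a median of -0.57 (camera adjusted p = 5.53e-18, and adjusted p = 0.934 with an estimated correlation). An intensity trend left by normalization is argued against, since cyclic loess left a median of 0.67 (adjusted p = 1.44e-18) while moving all probe sets by a median of 0.0558. Whether Erg day 0 replicate 2 carries the shift could not be decided: without it the median was 0.37, near the bound of 0.36 set at 50% of the full value, with an SD of 0.21 between the control arrays. More DNA, or a stronger response to it, may also raise these genes, and the inflammatory and NF-kB list, at -0.0266, does not decide it. An effect of Erg itself, of the promoter or of the day stays open and untested.

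In the average over both days, 4 of 34 splits of the arrays, the real one counted and the split of day 0 from day 1 left out because the fit holds day as a term, gave an interferon median as large (real value 0.36, highest other 0.42) and 2 of 34 an ETS median as large (0.12 and 0.17), so chance was not excluded for these 2 lists. Among the 18 splits with 2 arrays of each day on each side, 2 gave such an interferon median (highest other 0.39) and 1, the real one, such an ETS median (highest other 0.11), but 18 splits are too few for a share under 0.05. The split that gave 0.39 kept both Erg arrays of day 0 together, so it held the day 0 shift itself. The interferon counts therefore cannot decide for or against chance. For the number of probe sets past the threshold the real value was 0, so all 34 splits had to give as many (highest other 0) and the count decides nothing.

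Both Erg probe sets were lower in the arrays labelled Erg on day 0, at -1.26 and -0.14, and without Erg day 0 replicate 2 they were at -0.66 and 0.03. The probe sets may lie outside the part of Erg in the plasmid, in which case the first value reads the cells' own transcript. An exchange of the Erg and control labels on day 0 could also lower both values, and the second, -0.14, lies within its SE of 0.20. The sequence of the plasmid is not in the files, so these explanations cannot be told apart.

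Besides the interferon list, 6 lists had Erg differences that differed between the days by a test of the difference itself: adipocyte 0.34, endothelial 0.19, hypoxia and glycolysis 0.28, joint 0.17, tendon and fibrous matrix 0.37 and p53 -0.26, all with adjusted p = 0.934 with an estimated correlation. Of these 6, 0 kept direction and call without Erg day 0 replicate 2 and 6 without Erg day 0 replicate 1, which is consistent with that array carrying the differences. Leaving out other single arrays also ended 2 to 5 of the calls, with the values given in the report. Some settings that kept every array also gave fewer calls. Of all 22 lists, 7 passed in the main fit and 3 with the mean of all probe sets of a symbol. With dim probe sets removed or after cyclic loess 4 passed, and 6 with a replicate block or a block within each day. A second quantile normalization or crossed numbers on day 0 gave 7. Whether Erg day 0 replicate 2 stands apart for a technical or a biological reason was not tested.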

How the results depend on the processing

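The crossed replicate block, and for the lists the normalizations, blocks and 4-array setting, were chosen after the data were seen. The counts for the 4 Erg comparisons were 0 in all settings that kept the 8 arrays. Leaving out 1 array gave 0 to 3397 on day 0, 0 to 219 for the average and 0 to 356 for the difference between days, the highest each time without Erg day 0 replicate 1, and 0 throughout on day 1. The lone array left in a group was assumed to vary like the other groups. The 2 Erg arrays of day 0 differed more than those, with an SD of 0.611 against 0.233 to 0.335. The counts without 1 of them therefore describe how far a single array lay from the controls. The 8922 between control days became 5076 with dim probe sets removed and 4252 with 1 probe set per symbol, where fewer were tested, 13973 with array weights, and 366 to 16506 without 1 array. With a replicate block it was 7110. Replicate deviations correlated at -0.613 on day 0 and 0.318 on day 1, so the numbers do not establish pairs. With crossed numbers on day 0 the Erg counts were 0.

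The correlation of the Erg differences, 0.110, was 0.182 with dim probe sets removed and -0.0913 to 0.385 without 1 array, negative without Erg day 0 replicate 1 (-0.0726), Erg day 1 replicate 1 (-0.0521) or control day 1 replicate 2. Among the lists called, those that reversed did so without Erg day 0 replicate 2: adipocyte on day 0, 0.0743 (-0.473 to 0.0743 over arrays), and, for the difference between days, tendon -0.0076 (to 0.87), p53 0.15 (from -0.57) and hypoxia -0.0210 (to 0.58). Of the 91 named results past the threshold 0 changed sign and 65 lost their call in at least 1 setting. The cause was not tested. The 4-array setting for the average and difference, the within-day block between days, and array weights or a trend in camera could not be run. Without detection calls, small changes in dim probe sets cannot be judged.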

Other observations

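These values were picked after the data were seen, and nothing in this part was tested. Erg day 0 replicate 2 differed from the other day 0 arrays in several gene groups. Its tendon and fibrous matrix genes had a median log2 intensity of 10.64, against 12.06 to 12.42 in the other 3. Adipocyte markers read 7.63, against 8.64 and 8.92 in the controls, matrix proteases and inhibitors were also lower than in the other 3 arrays, smooth muscle genes 7.64 against 8.35 to 8.46 and cell cycle genes 9.05 against 9.64 to 9.85. Immediate early genes read 10.73 against 10.12 to 10.27 and p53 targets 11.51 against 10.58 to 11.04.

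On day 1 the cell cycle median was 9.16 in Erg replicate 1, 8.21 in control replicate 1, 7.48 in control replicate 2 and 7.28 in Erg replicate 2. The interferon median, relative to the mean of the day 0 controls, was 0.37 in Erg day 0 replicate 1, 0.84 in Erg day 0 replicate 2, 0.15 and -0.15 in the controls, and -2.02 to -1.86 in the day 1 arrays.

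The authors' deposited q values were under 0.05 for 0 probe sets in the Erg comparisons within days, their average and their difference, and for 17667 between the control days, 8443 higher and 9224 lower, where the Benjamini-Hochberg count here was 8922, 5334 higher and 3588 lower. They were under 0.05 for 5641 probe sets between Erg day 1 and Erg day 0, 3998 higher and 1643 lower, a comparison in which promoter and day change together.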
